A study of Mus musculus with 53 samples.

How the data were processed

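Total RNA was extracted with Trizol and biotinylated cRNA was hybridised to Affymetrix mouse arrays, per the labels' protocols. Wild-type, Ezh2-null and Eed-null ES cells had been grown on feeder fibroblasts and left in tissue plates for a short time before harvest so that the feeders would attach and be depleted, per the same protocols. The authors deposited 1 linear intensity value per probe set and array, and how the values were summarised and scaled is not given in the sources used here. The values lay between 0.4 and 33985.898 signal units, and the array medians on the log2(value + 32) scale ranged over 0.2035, under the limit of 0.3 set for renormalisation, so the deposited intensity values were used as they stand. Depth has no counterpart here; the number of arrays per group limits the precision.

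Of 45037 probe sets, 34945 had exactly 1 gene symbol in the platform annotation, 932 had several and 9160 had none. The symbols of 34741 probe sets were matched through the gene identifier to a current gene table, which changed 0 of them. Probe sets with several symbols or none were not used. The probe set with the highest mean over all 53 arrays stood for its gene, which gave 18193 genes, and the 13796 whose probe set lay above its array's median in at least 2 arrays were tested. The probe sets of a gene can disagree, so the mean of all of them was an alternative.

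Groups were taken from the sample titles. The 18 comparisons were fitted with limma 3.58.1 in R 4.3.3 on log2(value + 32), with 1 mean for each of the 15 groups over all 53 arrays, 38 residual and 4.7 prior degrees of freedom, and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05 and at least 2-fold. The pseudocount of 32 understates the change of dim genes. Wild-type lines were pooled. Of 25 gene lists, the 23 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry. The latter tests whether the genes of a list move on balance one way. The design, the lists, the comparisons, the rule for naming genes and most alternatives were set before the data were examined. That rule took the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap (interactions: among called genes), or 4 and 4 in the comparisons of lesser weight. It also took up to 4 members of each list with the smallest p and its other called members, and always Ezh2, Eed, Ezh1, Suz12, Pou5f1, Nanog and Sox2.

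Arrays were compared before groups were averaged. From 3963 pairs of probe sets of the same gene, a score was computed as the leading component of their differences (38.2% of the variance). It split the arrays of days 2 and 6 into a second set of 14 arrays with scores from 19.3 to 28.7 and a first set with scores of -7.2 or less. The second set holds wild-type replicates 3 and 4 at day 2 and 3 to 5 at day 6, the Ezh2-null replicates of the same numbers and all Eed-null arrays of these days. The set was therefore added as a block, and each set was fitted alone; these alternatives, and the one with wild-type replicates 4 to 7 only at day 0, were chosen after seeing the data. Replicates with the same number deviated together in Ezh2-null and wild-type cells at day 2 (correlations from 0.56 to 0.7 over 4 pairs) and at day 6 (0.38 to 0.72 over 5 pairs), so these numbers were read as pairs. No label names pairs, and the sets follow the numbers. The shift between the sets correlated between the 2 genotypes at 0.73 at day 2 and 0.71 at day 6. The correlations of the replicates therefore cannot part pairs from sets. With the replicate block 18 and 411 genes were called there, against 17 and 408 without it.

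The other alternatives, which kept the probe set of each gene unless the probe sets were averaged, were quantile normalisation, arrays centred on their median, a pseudocount 4 times lower and 4 times higher, no filter or a filter at the 75th percentile, the mean of all probe sets, eBayes with a trend, array weights, only the arrays compared, cell line as a random block, the replicate block, 1 wild-type line at a time, no minimum fold or 1.5-fold, and each array left out in turn. The fit was tested on simulated data in which 50 genes each of 13796 were changed 3-, 4-, 8- and 16-fold: in the 18 comparisons all were recovered at 8- and 16-fold. At 3-fold 46 of 50 (92%) were recovered for the Eed-null interaction, 47 for Ezh2-null against wild type at day 8, 49 for the mutants at day 6 and for Sox1-GFP cells, and all elsewhere. At 4-fold 49 of 50 were recovered for Sox1-GFP cells and for MEF, and all elsewhere. The simulated noise was drawn independently for each array and gene, without array sets, cell lines or groups of unequal spread. The changes were added on the log2 scale of the fit, pseudocount included, so for a dim gene they stand for a larger change of signal. The recovered shares can therefore overstate the sensitivity on the real arrays, above all for dim genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.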

Results

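Gene expression was measured in mouse embryonic stem (ES) cells and in 4 differentiated cell types on 53 Affymetrix arrays in 15 groups. The study asked what the loss of Ezh2 or Eed does to gene expression in undifferentiated and in differentiating ES cells. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 and represses many developmental genes, and Eed is a subunit that the complex needs. Wild-type ES cells were sampled at day 0 (7 arrays) and at day 2 (4), day 6 (5) and day 8 (2) after withdrawal of LIF, the cytokine that holds ES cells undifferentiated. The lines were J1, CJ7 and E14tg1 at day 0, J1 and CJ7 at days 2 and 6, and CJ7 alone at day 8. Ezh2-null cells were sampled at the same days (6, 4, 5 and 2 arrays), and cells labelled Eed-null at day 0 (5), day 2 (2) and day 6 (2). The sample titles name no line for either mutant, so genotype cannot be told apart from line in any comparison of a mutant with wild type. The other groups were mesoendodermal cells carrying a GFP reporter of T (2), neuronal progenitors carrying a Sox1-GFP reporter (3), neuronal stem cells (2) and mouse embryonic fibroblasts, MEF (2). Array medians ranged from 50.5 to 63 signal units and trimmed means from 171.3 to 222, and the number of arrays per group limits the precision. The labels call the arrays of a group biological replicates without saying what was repeated, so the p-values below measure the spread between these samples. That spread was pooled over all 15 groups and was not taken from the groups compared alone. Sizes are log2 fold changes ± SE from the fit on log2(signal + 32), and levels are mean signal ± SD.

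The targeted gene came first. The Ezh2 probe set gave 1451 ± 247 in wild-type and 214 ± 31.6 in Ezh2-null cells at day 0 (n = 7 and 6), a change of -2.59 ± 0.13, adjusted p = 2.1e-19. The difference was -2.30 ± 0.16 at day 2, -2.68 ± 0.14 at day 6 and -1.86 ± 0.23 at day 8, and every Ezh2-null array lay below every wild-type array of its day. In the arrays labelled Eed-null, Ezh2 signal was 1152 ± 58.4 at day 0 (n = 5). The brighter of the 2 Eed probe sets was not lower in these arrays. It gave 2956 ± 129.9 against 2536 ± 276 in wild type at day 0, a difference of 0.23 ± 0.12, adjusted p = 0.14. The differences at day 2 (0.21 ± 0.18) and day 6 (0.51 ± 0.18) were also above 0. The dimmer Eed probe set stayed near background in all groups. The part of Eed that is altered in these cells is not given in the sources used here, so the Eed probe sets are no check of that label. Ezh1, the paralog of Ezh2, and Suz12, a further PRC2 subunit, were called in no comparison of Ezh2-null with wild-type cells.

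**Figure D1:**
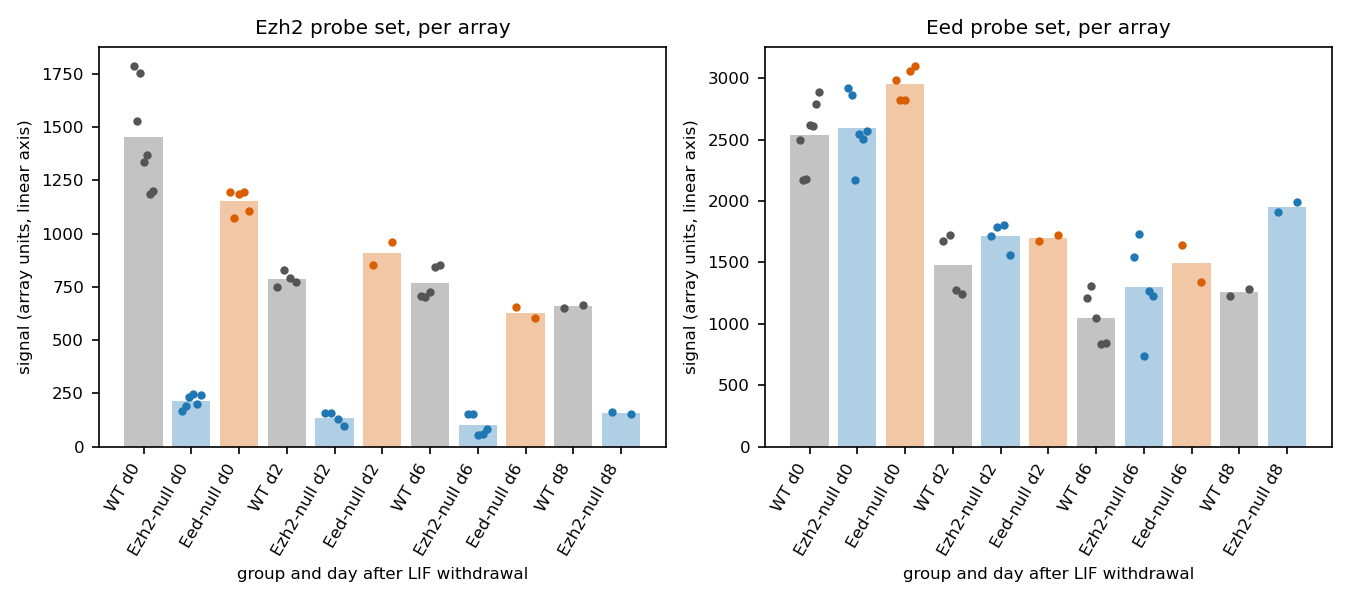
Signal of the Ezh2 and Eed probe sets on each array (linear axis, signal units) by group and day, with the mean of each group as a bar. Ezh2 signal in Ezh2-null arrays lies between 52.6 and 245.9, below all wild-type arrays, whereas Eed signal in the arrays labelled Eed-null lies within or above the wild-type values of the same day.

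In undifferentiated Ezh2-null cells none of the core pluripotency factors was called: Pou5f1, Nanog and Sox2 differed from wild type by 0.03 ± 0.17, 0.31 ± 0.21 and 0.05 ± 0.24 (n = 6 and 7). For Nanog, though not called, every Ezh2-null array lay above every wild-type array. Otx2, a homeobox factor of the primed epiblast, was higher by 1.31 ± 0.32, adjusted p = 0.033. Cd99, a cell surface glycoprotein, was higher by 1.94 ± 0.24, adjusted p = 1.2e-06, and AU040320 by 1.18, adjusted p = 0.034. Ezh2 itself, Usp17la, a deubiquitinase gene of the 2-cell stage (-1.63 ± 0.18, adjusted p = 5.8e-08), Gm20767 (-2.22 ± 0.18, adjusted p = 1.6e-11) and AF067061 (-1.38, adjusted p = 2.1e-09) were lower. Usp17la and Gm20767 have near-identical copies whose transcripts the probes may also detect, and AU040320 and AF067061 were named because so few genes were called. These were all 7 of the 13796 genes tested that passed in limma (3 higher and 4 lower), against 1488 at an unadjusted p under 0.05. Of 11 primed epiblast genes 1 rose, also when adjusted over the list alone, and the list lay above other genes (median 0.20, adjusted p = 0.0063, and adjusted p = 0.38 with an estimated correlation). Of the 4 genes of the 2-cell list 2 fell; the list was too short for a list test. Wild-type replicates 1 to 3 clustered apart from replicates 4 to 7 at day 0, and against replicates 4 to 7 alone Otx2 (0.90, adjusted p = 0.26) and AU040320 (0.16, adjusted p = 0.82) were not called. Both calls were also lost without wild-type replicate 1, 2 or 3 or any 1 of the Ezh2-null arrays (adjusted p = 0.055 to 0.088 for Otx2 and 0.056 to 0.11 for AU040320), and with cell line as a random block (adjusted p = 0.81 and 0.69). Usp17la missed the fold minimum with a pseudocount 4 times higher (-0.95). The count was 26 against wild-type replicates 4 to 7, 215 against the J1 arrays and 46 without E14tg1, and rose to 17 without wild-type replicate 4 and to 14 without replicate 5, 6 or 7.

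The arrays labelled Eed-null differed from wild type at day 0 in many more genes. By probe-set behaviour these arrays formed a cluster of their own, while the Ezh2-null arrays of day 0 clustered with wild-type replicates 4 to 7. The Eed-null array medians were also higher (58.3 to 62.2 against 50.5 to 54.6 in wild type). Genotype and a technical difference between the arrays therefore cannot be told apart here. The imprinted growth regulator Plagl1 was higher by 3.46 ± 0.42, adjusted p = 1.7e-08 and Nod1, a sensor of bacterial peptidoglycan, by 2.66 ± 0.09, adjusted p = 1.4e-25 (n = 5 and 7). Fos, an immediate early gene, rose by 2.34 ± 0.20, Hmga2, a chromatin factor of embryonic tissue, by 2.13 ± 0.22, and Pmaip1, a proapoptotic p53 target, by 2.13 ± 0.17. The germline genes Tex15 and Rhox6 rose by 2.30 ± 0.16 and 2.45 ± 0.40, and the zinc finger gene Zfp934 by 2.48 ± 0.13. The largest falls were those of Kbtbd11 (-2.95 ± 0.22, adjusted p = 3.9e-14), Dpys, an enzyme of pyrimidine breakdown (-2.95 ± 0.16), Lor (-2.69 ± 0.26) and the neuronal factor Neurod1 (-2.38 ± 0.28). They were followed by Aass (-2.15 ± 0.17), Foxp1 (-2.14 ± 0.13), Trub1 (-2.07 ± 0.23) and Tmem38b (-1.97 ± 0.33). These 16 genes were chosen among called genes whose arrays did not overlap between the 2 groups. In all, 303 genes passed (207 higher and 96 lower), and for 225 of them the arrays did not overlap. With the mean of all probe sets of a gene, Kbtbd11 (-0.71) and Tmem38b (-0.40) missed the fold minimum. With each array centred on its median the split became 132 higher and 181 lower, as the median over all genes moved from 0.042 to -0.095.

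Endoderm genes rose as a group at day 0 in the arrays labelled Eed-null: 8 of 22 were called higher, also when adjusted over the list alone, and none lower (adjusted p = 3.1e-06, and 0.049 with an estimated correlation). They included the basement membrane collagens Col4a2 (1.88 ± 0.19) and Col4a1 (1.76 ± 0.20), the visceral endoderm receptors Cubn (1.78 ± 0.24) and Amn (1.27 ± 0.15), the endocytic adaptor Dab2 (1.52 ± 0.20) and Sox17 (1.54 ± 0.33). Of 20 fibroblast genes 9 rose, also when adjusted over the list alone, among them Fbln2 (2.11 ± 0.49), Col1a1 (1.99 ± 0.53), Col1a2 (1.98 ± 0.41) and Lox (1.73 ± 0.48) (adjusted p = 7.1e-05, and 0.33 with an estimated correlation). Fibroblast genes varied from array to array within every genotype. Col1a1 signal was 9.4 or less in wild-type replicates 1 to 3 and 122.5 to 236.6 in replicates 4 to 7. It was 23.4 to 187.1 in Ezh2-null cells, and 517.9 to 787.6 in Eed-null replicates 1 to 4 against 9 in replicate 5. All 9 risen fibroblast genes were lowest in that replicate among the Eed-null arrays, as were 3 of the 8 risen endoderm genes. Of the 198 risen genes outside the fibroblast list 98 were lowest there too. Against wild-type replicates 4 to 7 alone, Col1a1 (0.96, adjusted p = 0.15), Fbln2 (1.00, adjusted p = 0.083) and Lox (0.73, adjusted p = 0.23) missed the threshold. The fibroblast list (median 0.68, adjusted p = 0.0031) and the endoderm list (median 0.64, adjusted p = 1.5e-05) still passed. Of 14 trophoblast genes 2 rose, the keratins Krt7 (1.56 ± 0.19) and Krt18 (1.43 ± 0.45), and 3 when adjusted over the list alone (adjusted p = 0.028, and 0.14 with an estimated correlation). Against wild-type replicates 4 to 7 the list's adjusted p was 0.12 and Krt18 differed by 0.00. The 24 Hox genes lay higher with no single member called (median 0.34, adjusted p = 0.0019, and 0.13 with an estimated correlation). Other developmental transcription factors also lay higher as a list (median 0.26, adjusted p = 0.018, and 0.049 with an estimated correlation), while Gli1 (-1.43 ± 0.19) fell. The 14 ribosomal protein genes lay lower with no member called (median -0.17, adjusted p = 0.0029, and 0.33 with an estimated correlation). Among single members of other lists, Hand1 (1.87 ± 0.31), the PRC1 gene Bmi1 (1.59 ± 0.23) and the nodal antagonist Lefty2 (1.26 ± 0.31) rose. The germline genes Rhox9 (1.92 ± 0.24) and Sycp1 (1.90 ± 0.11) and the imprinted genes Peg3 (1.64 ± 0.15) and Igf2 (1.53 ± 0.32) rose as well, and the pluripotency gene Dppa3 was called too (1.37 ± 0.24). The arrays of the 2 groups overlapped for Cubn, Dab2, Igf2, Krt18 and the 4 fibroblast genes named. With the mean of all probe sets, Dab2 (0.60), Igf2 (0.66) and Peg3 (0.88) missed the fold minimum. With only the arrays compared, Lox (adjusted p = 0.061) and Krt18 (adjusted p = 0.11) were not called. With a pseudocount 4 times higher, Sox17 (0.88), Amn (0.69) and Krt7 (0.85) missed the minimum. Against the J1 arrays alone Gli1 (-0.75) and Lefty2 (1.10, adjusted p = 0.084) were not called.

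The 2 mutants were also set against each other at day 0, in the absence of any wild-type array. Otx2 was higher in Ezh2-null than in Eed-null cells by 2.12 ± 0.35, adjusted p = 5.9e-06, and Kbtbd11 (2.96 ± 0.22), Dpys (2.67 ± 0.16), Trub1 (2.20 ± 0.23) and Lor (2.14 ± 0.27) were higher too (n = 6 and 5). With the mean of all probe sets Kbtbd11 (0.74) and Dpys were not called. Srgn, a proteoglycan core protein, was lower (-3.19 ± 0.28, adjusted p = 9.5e-12), as were Fos (-2.58 ± 0.21), Rhox6 (-2.40 ± 0.42) and Plagl1 (-2.33 ± 0.44). Of 22 endoderm genes 8 were lower in Ezh2-null cells, also when adjusted over the list alone (adjusted p = 8.7e-08, and 0.037 with an estimated correlation), and of 20 fibroblast genes 9 (adjusted p = 2.2e-05, and 0.23 with an estimated correlation). In all, 101 genes were higher and 192 lower; with each array centred on its median the split was 170 and 121. Between the lists of genes called against wild type at day 0, 3 genes were shared in the same direction (2 higher and 1 lower). Unchanged groups simulated against the same 7 wild-type arrays shared at most 1 gene in 50 simulations, independent lists of these sizes would share 0 in either direction, and over 35 splits of the wild-type arrays the count was 1 to 5. The covariance of the log2 fold changes over genes was 0.0154, against 0.0084 from the shared arrays alone, and their correlation was 0.22, against 0.44.

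In wild-type cells the withdrawal of LIF was followed at day 2 by changes in single genes of the epiblast, the streak and naive pluripotency; the lists were not tested at this day. Fgf5, a growth factor of the primed epiblast, rose by 3.64 ± 0.39, adjusted p = 9.7e-10, Pim2, a kinase of the same stage, by 2.68 ± 0.27, and the streak genes Fgf8 and Eomes by 2.52 ± 0.31 and 2.33 ± 0.31 (n = 4 and 7). Socs3, a direct target of LIF signalling, fell (-3.51 ± 0.13, adjusted p = 1e-23), together with the naive factors Klf4 (-2.99 ± 0.23), Nr0b1 (-2.78 ± 0.30) and Tfcp2l1 (-2.36 ± 0.28; -0.74 and not called with the mean of all probe sets). The myoblast fusion gene Mymx (-3.36 ± 0.35) and Phf11d (-2.84 ± 0.25) fell as well. In all, 195 genes were higher and 268 lower. The day 2 arrays fall into 2 sets by probe-set behaviour, J1 in the first and CJ7 in the second, and 530 genes were called with the set as a block (295 and 235), while the J1 arrays alone gave 822 and the second set 948.

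At day 6 the wild-type cells expressed genes of the primitive streak and of mesoderm. Aplnr, a receptor of migrating mesoderm, rose from 12.3 ± 2.20 to 918 ± 279, or by 4.38 ± 0.12, adjusted p = 3.4e-29 (n = 5 and 7). Mixl1, a homeobox factor of the streak, rose from 25.0 ± 6.70 to 1247 ± 836, or by 4.11 ± 0.28. Amot (5.21 ± 0.26), the actin gene Acta1 (4.45 ± 0.48), the myelin protein gene Pmp22 (3.92 ± 0.12), Igfbp4 (3.88 ± 0.18), the keratin Krt18 (3.78 ± 0.45) and Wls, which Wnt secretion needs (3.71 ± 0.24), also rose. Pluripotency factors fell, among them Nr0b1 (-4.42 ± 0.28), Fbxo15 (-3.79 ± 0.20), Sox2 (-2.88 ± 0.26), Nanog (-2.12 ± 0.22) and Pou5f1 (-1.86 ± 0.18). The germ cell gene Morc1 (-4.02 ± 0.27), Dnmt3l, a cofactor of de novo DNA methylation (-3.73 ± 0.23), Phf11d (-3.73 ± 0.23), Hsd17b14 (-3.60 ± 0.17), Mylpf (-3.59 ± 0.29) and Enox1 (-3.58 ± 0.26) had the largest other falls. Eed was lower by the fold minimum or more (-1.26 ± 0.12; -0.94 with the array set as a block and -0.62 with the mean of all probe sets), whereas the change of Ezh2 (-0.88 ± 0.13) missed it. In all, 800 genes were higher and 598 lower; with the array set as a block 942 and 425 were called, and the first and second set alone gave 1383 and 1716.

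The lists moved at day 6 as follows, and for every list the counts were the same when adjusted over the list alone. Of 20 primitive streak and mesoderm genes 14 rose and none fell (median 2.05, adjusted p = 3e-08, and 0.03 with an estimated correlation), and of 26 naive pluripotency genes 22 fell and 1 rose (adjusted p = 1.5e-16, and 0.03 with an estimated correlation). A further 4 lists held with an estimated correlation: cardiac and muscle (7 of 18 higher, adjusted p = 0.013), Wnt, BMP and FGF signalling (16 higher and 2 lower of 34, 0.037), imprinted (12 of 28 higher, 0.037) and germline (7 of 17 lower, 0.037). With the preset correlation alone 7 more lists passed: endoderm (9 of 22 higher; adjusted p = 0.087 with an estimated correlation), Hox (4 of 24 higher; 0.087), and blood and endothelium (4 of 15 higher; 0.13). The others were trophoblast (6 higher and 1 lower of 14; 0.067), fibroblast (8 of 20 higher; 0.53), PRC2 (3 of 11 lower; 0.086) and DNA methylation (4 of 12 lower; 0.17). The other 10 lists tested did not pass: PRC1 (2 higher and 3 lower of 17), primed epiblast (2 and 2 of 11), neural (2 and 3 of 27), and glia and neural stem cell (3 higher of 16). Nor did other developmental transcription factors (5 and 4 of 45), cell cycle inhibitors (4 higher of 13), p53 targets (2 higher of 17), glycolysis and hypoxia (3 lower of 20), proliferation (1 and 1 of 26) and ribosomal protein (0 of 14). The lists of the 2-cell stage (2 of 4 lower) and of the sex chromosomes (1 of 4 lower) had too few measured members for a test.

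At day 8 embryonic globins led the rise in wild-type cells. Hbb-bh1 rose by 6.61 ± 0.73, adjusted p = 7.7e-10, Hbb-y by 6.46 ± 0.45 and Hba-x by 5.32 ± 0.51, all of them globins of primitive red cells, and Postn, an extracellular matrix protein, by 5.16 ± 0.68 (n = 2 and 7). Dnmt3l (-3.37 ± 0.31), Gng3 (-3.17 ± 0.24), Hsd17b14 (-3.17 ± 0.24), Nr0b1 (-3.15 ± 0.39) and Pou5f1 (-2.34 ± 0.25) fell. In all, 1013 genes were higher and 501 lower; with each array centred on its median the split was 786 and 767, as the median over all genes moved from 0.05 to -0.106. The 2 day 8 arrays are of CJ7, whereas the 7 day 0 arrays are of 3 lines; against the CJ7 arrays of day 0 alone 1567 genes were called (1013 and 554). The globin probes may detect more than 1 member of the family.

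At day 2 few genes separated Ezh2-null from wild-type cells. Zic1, a neural zinc finger factor, was higher by 1.88 ± 0.25, adjusted p = 6.7e-06, and the cell cycle inhibitor Cdkn2b by 1.21 ± 0.26 (n = 4 and 4). The germline gene Tex19.1 (1.55 ± 0.29, but 0.52 and not called within the first array set) and Mfsd12 (1.39 ± 0.15) were higher too, and Prickle1, a gene of planar cell polarity, was lower (-1.31 ± 0.27, adjusted p = 0.0083). These calls depended on the model, except that of Mfsd12. With only the arrays compared, Zic1 (adjusted p = 0.21), Tex19.1 (adjusted p = 0.28) and Prickle1 (adjusted p = 0.27) were not called. With cell line as a random block, Cdkn2b (adjusted p = 0.37), Tex19.1 (adjusted p = 0.17) and Prickle1 (adjusted p = 0.17) were not. With Ezh2 itself, 15 genes were higher and 2 lower, against 1269 at an unadjusted p under 0.05. Of 26 naive pluripotency genes none was called over all genes and 1 rose when adjusted over the list alone; the list lay higher (median 0.50, adjusted p = 9.6e-08, and 0.16 with an estimated correlation). The germline list also lay higher with no member called (median 0.38, adjusted p = 0.032 with an estimated correlation), as did cardiac and muscle, with 1 member called when adjusted over the list alone (median 0.14, 0.032). Trophoblast (adjusted p = 0.12 with an estimated correlation), p53 targets (0.8) and, on the lower side, primed epiblast (0.14) passed with the preset correlation only. With the array set as a block 22 genes were called (20 higher and 2 lower), and the replicate block gave 18. Within the first set 50 genes were called and within the second 105, of which 6 were higher and 2 lower in both and 4 went opposite ways, with a correlation of 0.11 over genes. Fgf8 was among the latter, at 1.27 in the first set and -1.27 in the second, and p53 targets had a median of 0 in the first set.

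In cells labelled Eed-null at day 2, the muscle light chain gene Mylpf (2.57 ± 0.43), Tex19.1 (2.34 ± 0.35) and Nod1 (2.30 ± 0.14, adjusted p = 2e-16) were higher than in wild type (n = 2 and 4). Dnmt3l was higher by 2.00 ± 0.34. Kbtbd11 (-2.67 ± 0.32; -0.98 with the mean of all probe sets), Trub1 (-2.54 ± 0.33) and Serinc5 (-2.04 ± 0.36) were lower. In all, 64 genes were higher and 76 lower. Of 24 Hox genes 1 rose, also when adjusted over the list alone (median 0.29, adjusted p = 3.3e-06, and 0.03 with an estimated correlation). Of 17 germline genes 4 rose (0.2 with an estimated correlation), of 26 naive pluripotency genes 2, and 3 when adjusted over the list alone (0.4), and endoderm lay higher with no member called (0.27). Both Eed-null arrays of this day lie in the second array set. Within that set 177 genes were called (95 and 82), the block gave 127, and the count was 76 without Eed-null replicate 1 and 65 without replicate 2.

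Genes of the primitive streak were lower in Ezh2-null than in wild-type cells at day 6. Aplnr gave 37.3 ± 23.4 against 918 ± 279 in wild type (-3.79 ± 0.13, adjusted p = 2.9e-25), and Mixl1 (-3.53 ± 0.30), Eomes (-3.05 ± 0.31), Lhx1 (-3.07 ± 0.18) and Fgf8 (-2.90 ± 0.32) were lower as well (n = 5 and 5). The embryonic globin Hbb-bh1 (-3.42 ± 0.58; -6.69 within the first array set and -1.24 within the second), Igfbp3 (-3.16 ± 0.40) and the immunoproteasome subunit Psmb10 (-3.0 ± 0.20) completed the largest falls. Zic1 gave 576 ± 242 against 28.7 ± 11.8, higher by 3.25 ± 0.22, adjusted p = 6e-15. The cell cycle inhibitors Cdkn2a (433 ± 145 against 42.7 ± 17.5, 2.62 ± 0.19, adjusted p = 7.1e-14) and Cdkn2b (2.63 ± 0.23) rose. So did Parm1 (3.10 ± 0.15), the semaphorin Sema3c (2.80 ± 0.24), Npnt, an extracellular matrix protein (2.46 ± 0.21), the cholesterol transporter Abca1 (2.32 ± 0.20) and Fam124a (2.14 ± 0.19). These 16 genes were chosen among called genes whose arrays did not overlap between the 2 groups, which held for 285 of all 408 called. Nanog and Sox2 were higher than in wild type, by 1.22 ± 0.24, adjusted p = 9.6e-05 and 1.33 ± 0.28, adjusted p = 0.00026, with overlapping arrays, as Ezh2-null replicate 3 gave 222.8 for Nanog and 249.3 for Sox2. The imprinted gene Grb10, which restrains growth, was lower (-2.72 ± 0.69; -1.30, adjusted p = 0.2 within the second set and -0.61, adjusted p = 0.53 with array weights). With only the arrays compared, Nanog (adjusted p = 0.11), Sox2 (adjusted p = 0.13), Grb10 (adjusted p = 0.1) and Hbb-bh1 (adjusted p = 0.075) were not called.

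In all, 252 genes were higher and 156 lower in Ezh2-null cells at day 6. Of 20 primitive streak and mesoderm genes 11 were lower and none higher, also when adjusted over the list alone (median -1.25, adjusted p = 3e-11, and 0.018 with an estimated correlation). The list median was -0.62 within the first set and -1.50 within the second. Of 13 cell cycle inhibitors 4 were higher, also when adjusted over the list alone, among them Cdkn1a (1.18 ± 0.20; 0.69 and not called within the first set) (adjusted p = 0.0012, and 0.031 with an estimated correlation). Of 26 naive pluripotency genes 13 were higher, also when adjusted over the list alone (adjusted p = 8.9e-07, and 0.19 with an estimated correlation). Other lists passed with the preset correlation only. Of 17 p53 targets 4 were higher, among them the death receptor gene Fas (1.26 ± 0.13; 0.72 and not called within the first set) (adjusted p = 0.12 with an estimated correlation). Of 26 proliferation genes 6 were lower, such as Plk1 (-1.11 ± 0.16) and Birc5 (-1.06 ± 0.16), and Ccnd2 (1.42 ± 0.19) was higher (0.2); without Ezh2-null replicate 3, Plk1 (-0.88) and Birc5 (-0.78) missed the fold minimum. Of 15 blood and endothelium genes 4 were lower (0.19), of 34 genes of Wnt, BMP and FGF signalling 2 were higher and 4 lower (0.12), and of the trophoblast and germline genes 2 each were higher (0.12 and 0.27). These counts were the same when adjusted over each list alone. Hox genes went both ways, with Hoxc13 (1.48 ± 0.13) higher and Hoxb2 (-1.78 ± 0.22) lower. With a pseudocount 4 times higher, Hoxc13 (0.76), Hoxb2 (-0.97), Fas (0.61), Plk1 and Birc5 (-0.98) missed the fold minimum. With the array set as a block 254 genes were higher and 158 lower, and the replicate block gave 411 in all. Within the first set 280 genes were called and within the second 779, of which 93 were higher and 54 lower in both and 2 went opposite ways. The proliferation genes lay lower in the second set (16 of 26, median -1.22) and not in the first (0 of 26, median -0.15). The blood genes fell in the first (6 of 15, median -0.68) more than in the second (2 of 15, median 0.03). These differences between the sets were not tested.

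**Figure D2:**
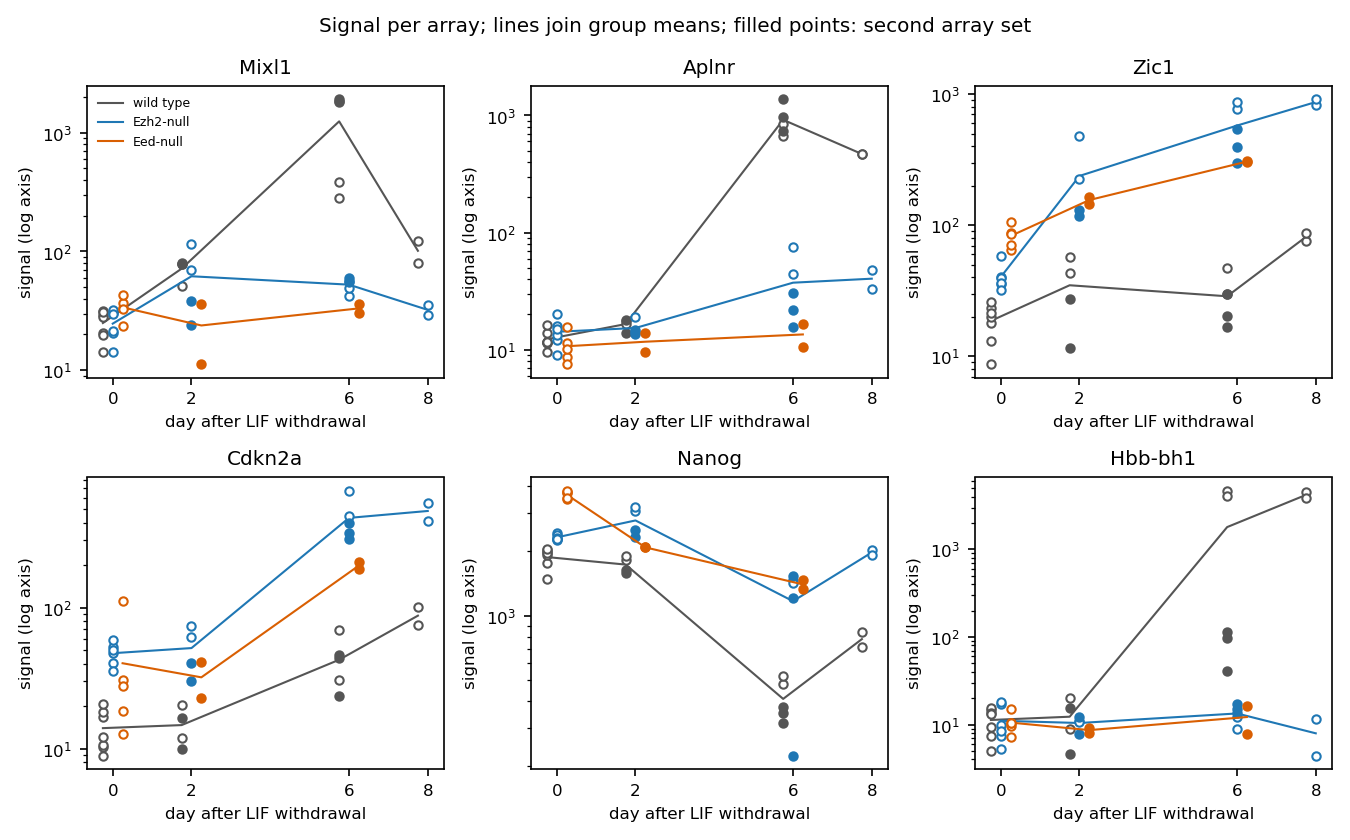
Signal of Mixl1, Aplnr, Zic1, Cdkn2a, Nanog and Hbb-bh1 on each array by day after LIF withdrawal (log axis, signal units) in wild-type, Ezh2-null and Eed-null cells, with filled points for the second array set, open points for the first set and for the other arrays, and lines through the group means. Mixl1 and Aplnr rise in wild type at day 6 (Aplnr to a mean of 918.5) and stay low in both mutants (37.3 in Ezh2-null), while Zic1 rises in the mutants (575.7 in Ezh2-null).

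Cells labelled Eed-null differed from wild type at day 6 in many of the same genes. Aplnr (-4.34 ± 0.18, adjusted p = 9.8e-23), Mixl1 (-3.90 ± 0.40), Eomes (-3.21 ± 0.41) and Lhx1 (-3.24 ± 0.23) were lower, as were Hbb-bh1 (-3.46 ± 0.76; -1.34 within the second set), Igfbp3 (-3.41 ± 0.53) and Psmb10 (-3.19 ± 0.26) (n = 2 and 5). Esx1, a homeobox gene of the placenta, was higher by 3.36 ± 0.17, adjusted p = 4.3e-19 and the keratin Krt7 by 2.58 ± 0.27. Mylpf (3.15 ± 0.42), Parm1 (2.70 ± 0.20), Tinagl1 (2.56 ± 0.29), Zic1 (2.50 ± 0.29), Tex19.1 (2.50 ± 0.34) and the fatty acid binding gene Fabp3 (2.46 ± 0.24) were higher too. Nanog (1.72 ± 0.31), Sox2 (1.66 ± 0.37), Cdkn2a (1.65 ± 0.26) and Cdkn2b (1.77 ± 0.31) also lay above wild type and were called. Of 13 cell cycle inhibitors 2 were higher and 1 lower, Cdkn1c (-1.20 ± 0.36), also when adjusted over the list alone, and the list did not pass (adjusted p = 0.071). Cdkn1c was not called with cell line as a random block (adjusted p = 0.075), with the array set as a block (-0.93) or without either Eed-null array (adjusted p = 0.15 and 0.14). With only the arrays compared, Hbb-bh1 was not called (adjusted p = 0.23), and with a pseudocount 4 times higher Cdkn2a (0.94) missed the fold minimum. In all, 253 genes were higher and 165 lower. Of 20 streak and mesoderm genes 11 were lower, also when adjusted over the list alone (median -1.25, adjusted p = 5.1e-11, and 0.011 with an estimated correlation). Of 14 trophoblast genes 4 were higher (adjusted p = 0.0022 with an estimated correlation). Of 24 Hox genes 4 were higher, such as Hoxd9 (1.62 ± 0.21) and Hoxa10 (1.21 ± 0.14; 0.49 with the mean of all probe sets), and 2 lower (0.029). Of 26 naive pluripotency genes 15 were higher, with 1 lower when adjusted over the list alone (0.071). Of 28 imprinted genes 4 were higher and 2 lower, or 3 over the list alone (0.36). Of 17 germline genes 3 were higher (0.36) and of 17 p53 targets 1 (0.21). These 4 lists passed with the preset correlation only. Both Eed-null arrays lie in the second array set, within which 475 genes were called (311 and 164) and the streak list had a median of -1.42; the block gave 287 and 130.

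The genes called in the 2 mutants at day 6 overlapped. Of the 408 genes called in Ezh2-null and the 418 in Eed-null cells, 122 were higher in both, 82 were lower in both and none went opposite ways. Independent lists of these sizes would share 4.6 and 1.9 genes, and unchanged groups simulated against the same wild-type arrays shared at most 1 in 50 simulations. With the wild-type arrays split between the 2 comparisons the shared genes numbered 81 to 117 higher and 54 to 77 lower over 20 splits. The covariance of the log2 fold changes was 0.1216, against 0.0118 from the shared arrays alone and a median of 0.1156 with split controls. Their correlation was 0.71, against 0.38 from the shared arrays alone. With split controls the correlation was 0.19 to 0.75 over the 20 splits, with a median of 0.64. Set directly against each other at day 6, Ezh2-null cells had more Fxyd6 (2.45 ± 0.27), H13 (2.09 ± 0.26) and Smim10l1 (2.04 ± 0.22) than Eed-null cells (n = 5 and 2). With the mean of all probe sets H13 (0.39) and Smim10l1 (0.72) missed the fold minimum, and with only the arrays compared Fxyd6 was not called (adjusted p = 0.054). They had less Esx1 (-2.66 ± 0.17, adjusted p = 5.2e-15) and Wfdc2 (-1.99 ± 0.21), apart from Ezh2 itself. In all, 55 genes were higher and 43 lower; within the second set 235 were called, the replicate block gave 885, and the count was 60 without Eed-null replicate 2.

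At day 8 the embryonic globins were nearly absent from Ezh2-null cells. Hbb-bh1 gave 8.00 ± 5.00 against 4177 ± 404 (-6.72 ± 0.91, adjusted p = 4.6e-06), with Hbb-y (-6.54 ± 0.56) and Hba-x (-5.13 ± 0.63) lower as well (n = 2 and 2). Zic1 was higher by 2.99 ± 0.35, adjusted p = 3.1e-07, Nexmif by 2.66 ± 0.36, Dnmt3l by 2.65 ± 0.39, Cdkn2a by 2.10 ± 0.31 and the pluripotency factor Pou5f1 by 1.63 ± 0.31. In all, 104 genes were higher and 36 lower. Of 15 blood and endothelium genes 6 were lower, also when adjusted over the list alone (adjusted p = 1.5e-15, and 4.9e-05 with an estimated correlation). Of 26 naive pluripotency genes 8 were higher, and 15 when adjusted over the list alone (0.031). The lists of primed epiblast (2 of 11 higher, 4 over the list alone, 0.041), germline (2 of 17, 3, 0.04), DNA methylation (2 of 12, 3, 0.04) and, on the lower side, endoderm (2 of 22, 3, 0.04) and cardiac and muscle (0 of 18, 1, 0.04) also held with an estimated correlation. Streak and mesoderm genes (3 of 20 lower; 0.15 with an estimated correlation), cell cycle inhibitors (1 of 13 higher; 0.072) and 4 more lists passed with the preset correlation only. The count was 46 without wild-type replicate 1, when Pou5f1 was not called (adjusted p = 0.076), and 80 without Ezh2-null replicate 2.

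The interaction asked whether the response to LIF withdrawal from day 0 to day 6 differed between mutant and wild-type cells. For Ezh2-null cells the response was smaller for Aplnr (-3.85 ± 0.18, adjusted p = 1.5e-20), Mixl1 (-3.52 ± 0.40), Eomes (-3.15 ± 0.42), Lhx1 (-3.04 ± 0.24) and Fgf8 (-2.94 ± 0.42) (n = 5, 6, 5 and 7). It was larger for Parm1 (3.04 ± 0.20), Sema3c (2.85 ± 0.31) and Zic1 (2.73 ± 0.30). Of 20 streak genes 12 were lower (0.021 with an estimated correlation) and of 13 cell cycle inhibitors 4 higher (0.033), with the same counts when adjusted over the list alone. In all, 242 genes were higher and 169 lower, and 429 were called with the array set as a block. For Eed-null cells 309 genes were higher and 325 lower. Cdh11 (-4.54 ± 0.88, adjusted p = 0.00027), Aplnr (-4.29 ± 0.22), Mixl1 (-4.11 ± 0.48) and the collagen Col1a1 (-3.50 ± 0.92) were lower. Lor (3.10 ± 0.45), Dpys (2.95 ± 0.28), Nr0b1 (2.74 ± 0.50) and Esx1 (2.54 ± 0.21) were higher. Lor and Dpys were already near background in Eed-null cells at day 0 (mean signal 7.5 and 13.1) and could hardly fall further. Their interactions therefore reflect the day 0 difference and show no altered response. Cdh11 and Col1a1 were higher in Eed-null than in wild-type cells at day 0, by 1.59 and 1.99. That difference is part of their interactions. Of 20 streak genes 11 were lower (0.028), and of 20 fibroblast genes, which varied from array to array at day 0, 10, or 13 over the list alone (0.17). With each array centred on its median the Eed-null split was 500 higher and 225 lower.

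**Figure D3:**
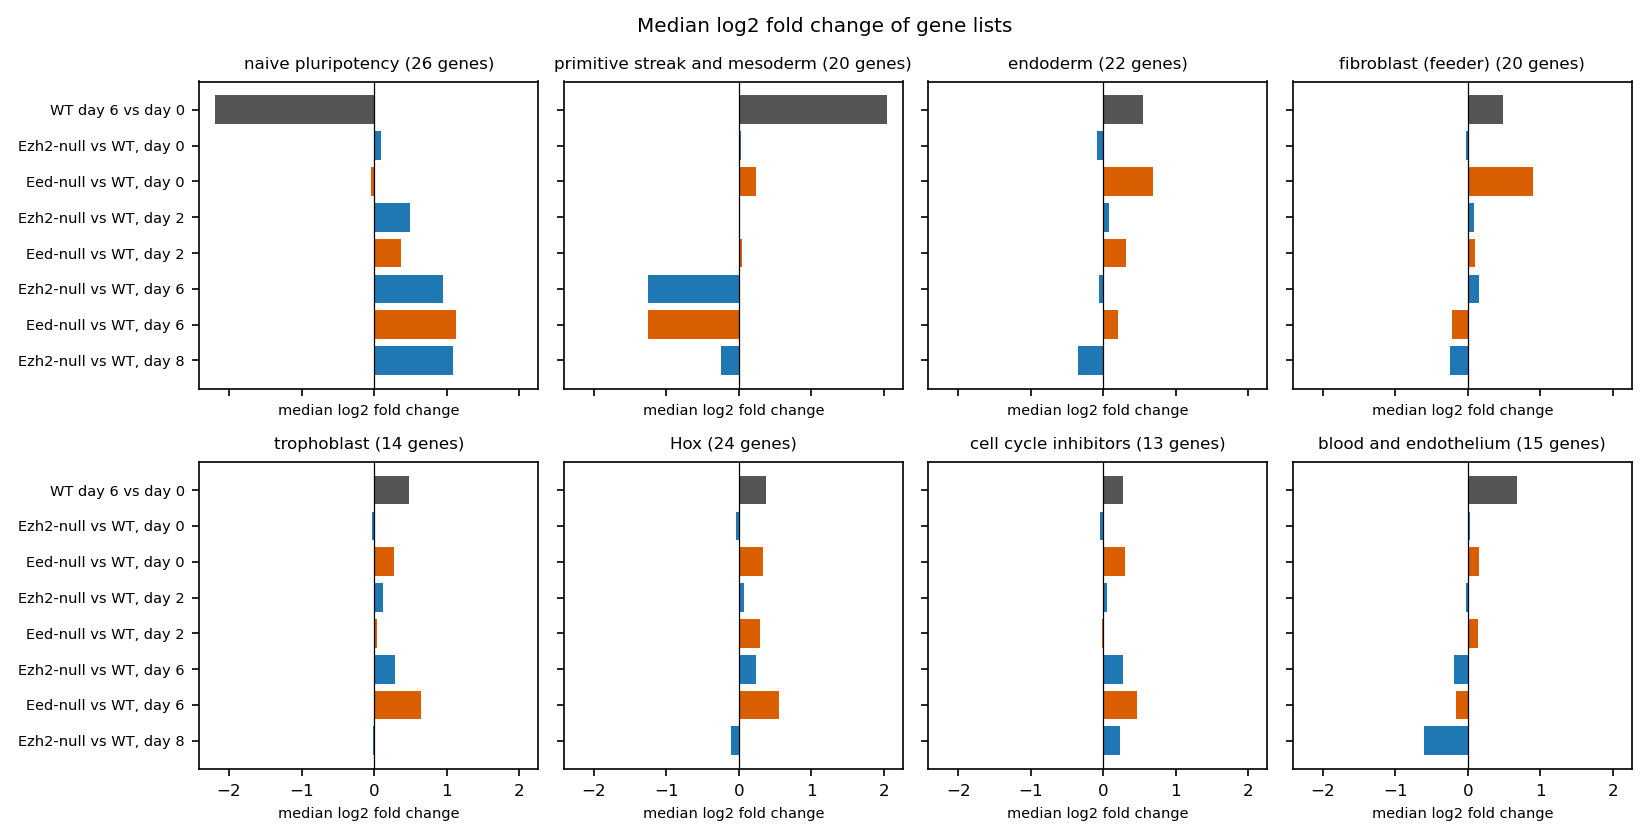
Median log2 fold change of 8 gene lists in each comparison of a mutant with wild type of the same day and in wild-type day 6 against day 0 (bars on a linear axis), with the number of measured members of each list in its title. The streak and mesoderm list lies at 2.05 in wild type at day 6 against day 0 and at -1.25 in both mutants against wild type at day 6.

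The other cell types were set against undifferentiated wild-type cells (7 arrays). Mesoendodermal T-GFP cells had more Amot (5.22 ± 0.36), Mixl1 (5.06 ± 0.38, adjusted p = 1.9e-14), Fgf8 (4.57 ± 0.40) and Aplnr (4.34 ± 0.17) (n = 2). They had less Morc1 (-5.01 ± 0.37), Nr0b1 (-4.95 ± 0.39), Phf11d (-4.39 ± 0.32) and the naive marker Zfp42 (-4.39 ± 0.38). Of 20 streak and mesoderm genes 13 were higher (0.0074 with an estimated correlation), of 34 Wnt, BMP and FGF genes 16 were higher and 3 lower (0.0074), and of 26 naive pluripotency genes 20 were lower and 1 higher (0.012). In Sox1-GFP neuronal progenitors the brain fatty acid binding protein gene Fabp7 was higher by 5.99 ± 0.13, adjusted p = 9e-34, with Ptn (5.46 ± 0.31) and the retinoic acid binding genes Crabp2 (5.70 ± 0.27) and Crabp1 (5.04 ± 0.18) (n = 3). Morc1 (-4.52 ± 0.32), Zfp42 (-4.25 ± 0.32), Dnmt3l (-4.22 ± 0.27) and Sgk1 (-3.86 ± 0.20) were lower. Of 27 neural genes 11 were higher (0.00026), of 16 glia and neural stem cell genes 7 (0.0088) and of 45 other developmental transcription factors 11, with 1 lower (0.0088). In these cells 22 of 26 naive pluripotency genes were lower and 1 higher (0.0088). Neuronal stem cells had more Ptn (7.10 ± 0.36, adjusted p = 3.8e-21), Fabp7 (6.66 ± 0.16), Gpm6b (6.52 ± 0.25) and the neural factor Pou3f3 (6.18 ± 0.12) (n = 2). They had less Tdgf1 (-6.76 ± 0.37), Zfp42 (-6.57 ± 0.38), Dppa5a (-6.41 ± 0.22) and Stmn2 (-6.31 ± 0.31). In them 9 of 16 glia and neural stem cell genes were higher (3.4e-05) and 25 of 26 naive pluripotency genes lower (0.013). Fibroblasts had more C1qtnf1 (7.64 ± 0.20, adjusted p = 1e-31), and the matrix genes Mgp (6.24 ± 0.30), Efemp1 (6.10 ± 0.35) and Col3a1 (6.04 ± 0.42) (n = 2). They had less Bex1 (-7.10 ± 0.09), the glucose transporter Slc2a3 (-6.89 ± 0.09), Dppa5a (-6.79 ± 0.22) and Rps4l (-6.71 ± 0.14). Of 20 fibroblast genes 19 were higher (4.5e-11, and 0.073 with an estimated correlation) and of 26 naive pluripotency genes 22 lower (0.028). The list counts in this paragraph were the same when adjusted over the list alone. The calls numbered 740 higher and 533 lower in T-GFP cells, 1236 and 558 in Sox1-GFP cells (952 and 682 after quantile normalization), 1647 and 1492 in neuronal stem cells (1348 and 1914 with each array centred on its median) and 1926 and 1346 in fibroblasts.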

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

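The tests on labelling, on the Y-linked genes, on the feeder share, on fibroblast RNA that varies between arrays, on the risen and fallen day 6 genes taken apart and on the streak list by array set were chosen after the result was seen. The splits of the arrays, the probe-set test, the test on risen genes outside the fibroblast list and the share of all called genes on the wild-type course were planned. By the interaction, 411 genes were called for Ezh2-null and 634 for Eed-null cells as differing from wild type in the response to LIF withdrawal. Chance could not be excluded for the Ezh2-null count, as given below. For Ezh2-null cells the differences of the genes named were -3.85 for Aplnr, -3.52 for Mixl1, -3.15 for Eomes, -3.04 for Lhx1, -2.94 for Fgf8, 3.04 for Parm1, 2.85 for Sema3c and 2.73 for Zic1. For Eed-null cells they were -4.54 for Cdh11, -4.29 for Aplnr, -4.11 for Mixl1, -3.50 for Col1a1, 3.10 for Lor, 2.95 for Dpys, 2.74 for Nr0b1 and 2.54 for Esx1. Those of Lor and Dpys reflect their signal near background in Eed-null cells at day 0. Those of Cdh11 and Col1a1 include their higher signal in Eed-null arrays at day 0.

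Of 112 groups of values tested for an array far from the others, 7 had one, where chance gives about 1 in 20. Ezh2-null replicate 3 at day 6 was lowest for Nanog (222.8, the next 1209.6) and for Sox2 (249.3, the next 1524.5). Wild-type replicate 1 at day 2 was lowest for Mixl1 (50.9, the next 78.1). Eed-null replicate 1 at day 0 was highest for Cdkn2a (111.7, the next 30.7), and Ezh2-null replicate 3 at day 0 was highest for Zic1 (58, the next 40.5). The array median was lowest in Eed-null replicate 2 at day 0 (58.3, the next 61.3) and the trimmed mean highest in wild-type replicate 2 at day 6 (204.6, the next 198.5).

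Other splits of the same arrays show where chance can be excluded. It can for Eed-null cells at day 0 (1 of 100 splits gave as many calls; 303 against at most 127 in the others) and Ezh2-null against Eed-null cells at day 0 (293 against 136). The Eed-null arrays of day 0 form a cluster of their own, so these splits cannot part genotype from array cluster. It can for wild type at day 2 (463 against 215) and day 6 (1398 against 817) and for Sox1-GFP cells (1794 against 550). None of these groups shares an array cluster with wild type at day 0. These splits therefore cannot part day or cell type from array cluster either. It cannot for Ezh2-null cells at day 0, where 5 of 100 splits gave 7 genes or more and the highest, with wild-type replicates 1 to 3 together, gave 43. It cannot for Ezh2-null cells at day 2 either, where 2 of 35 splits gave 17 or more; the other one follows the array sets and called 514 genes, and the call count with the set as a block was 22. Nor can it for the Ezh2-null interaction (5 of 100 splits, 411 against 432), where the blocked count was 429. Of the 4 other splits with as many genes, 3 put the first-set arrays of day 6 together, and 1 keeps the true groups of day 6, so that it still holds the day 6 difference. The interaction splits ignore the pairs of day 6, and none that part every pair were run. For Ezh2-null cells at day 6, 1 of 100 splits gave as many calls (408 against 314), but these splits ignore the pairs. Among splits that part every same-numbered pair, 8 at day 2 and 16 at day 6, the splits are too few for a share under 0.05; the real values were 17 and 408 and the highest others 6 and 160.

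The second array set stood apart from the first at days 2 and 6 in wild-type and Ezh2-null cells alike. The shift of wild-type cells at day 2 correlated over genes with that of Ezh2-null cells at day 6, which share no array, at 0.66, and this is consistent with a difference in labelling or hybridization between the sets. The 2 Y-linked genes Eif2s3y and Uty argue against labelling as the cause of their own low signal in Ezh2-null replicates 3 and 4 at day 2, since the smaller of their differences from wild-type arrays of the same set was -1.11. A difference between the cultures stays open for the other genes: 2 probe sets of a gene shifted together with a correlation of 0.55 over 120 genes, 0.612 of the value for wild-type day 6 against day 0, between the bounds set for either reading. The wild-type lines differ between the sets at day 2, so that line and set cannot be told apart there.

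Fibroblast genes were higher in Eed-null arrays at day 0, and feeder fibroblasts, which the protocol depletes by plating, are a candidate source. Of the 51 genes brightest in MEF over ES cells 46 (0.902) lay higher in Eed-null than in wild-type arrays, and 7 of the 9 risen fibroblast-list genes (0.778) varied more among the wild-type arrays than they rose. At the 7.44% of MEF signal that the risen list genes need, 29 of the 51 (0.569), among them C1qtnf1 (0.399%) and Cxcl12 (0.174%), lay under 0.5 of the level. Bgn, by contrast, implied 23.4%. The share of 7.44% came from genes chosen for their rise, so this count cannot decide whether cells with the MEF profile were the source. Over the 51 genes the implied share had a median of 3.39% and quartiles of 0.909% and 6.47%. Of the 8 risen endoderm genes 1 (0.125) varied that much, and of the 198 risen genes outside the list a share of 0.278. Neither share decides, as more fibroblast RNA in Eed-null replicates 1 to 4 than in any wild-type array would not show in it. In Eed-null replicate 5, all 9 risen fibroblast genes lay under the highest wild-type array. So did 2 of the 8 endoderm genes and 50 of the 198, but these counts rest on a single array. Fibroblast RNA with the MEF profile was argued against for the 198, of which 9 (0.045) were reached at the median implied share. With another profile they stay open. An effect of the mutation on fibroblast genes stays open, since no group separates it from the state of the cultures.

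Primitive streak genes were lower and, with the preset correlation only, pluripotency genes higher in both mutants at day 6 (adjusted p = 0.19 and 0.071 with an estimated correlation), for which a slower course of the wild-type change is a possible explanation. It stays open for these genes, as their calls alone nearly fix a place between the wild-type day 0 and day 6 means. As the cause of all called genes in Ezh2-null cells it was argued against (143 of 408, 0.35). So it was for their risen genes as a whole (52 of 252, 0.206), while the fallen ones (91 of 156, 0.583) leave it open. In Eed-null cells the counts were 171 of 418 (0.409), 62 of 253 (0.245) and 109 of 165 (0.661). All these counts include genes that already differed at day 0, whose place at day 6 does not show the pace of the course. Plagl1 in Eed-null cells is one (11.14 against 7.68 in wild type at day 0, log2 scale). At day 0, 7 genes were called in Ezh2-null and 303 in Eed-null cells, so the Eed-null counts cannot decide. The array set was argued against for the streak list, whose median in Ezh2-null cells was -0.62 or lower in either set alone. Loss of Ezh2 or Eed as the cause stays a hypothesis, as it was seen and tested on the same arrays. The sample titles also name no line for the mutants, so a difference of line cannot be told apart from one of genotype.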

How the results depend on the processing

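The alternatives that keep an array set alone or as a block, or wild-type replicates 4 to 7 only, were chosen after the data were seen; all others were planned. The 18 counts of called genes stayed within 1.5 times with quantile normalisation, median centring, no filter, the stricter filter and a trend in eBayes. So did the 9 counts that involve day 2 or day 6 with the array set as a block; the other 9 have no such value. Of 7287 values for 252 gene results under the alternatives, 7143 kept direction and call, 133 lost the call, 5 gained one and 6 changed direction; of 726 values for 96 list results 603 kept both, 122 lost the call and 1 changed direction. Where a result moved, the cause was not tested, apart from the thresholds and pseudocounts, which act by construction.

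With only the arrays compared the counts became 7 for Ezh2-null at day 2, 221 for Ezh2-null at day 8 and 25 for Ezh2-null against Eed-null at day 6. Array weights gave 11, 51, 631 and 215 for Ezh2-null at days 0, 2, 6 and 8, 496 for Eed-null at day 2, 183 between the mutants at day 6 and 700 for the Ezh2-null interaction. A pseudocount 4 times lower gave 19 and 28 for Ezh2-null at days 0 and 2, 548 and 221 for Eed-null at days 0 and 2, 540 and 159 between the mutants at days 0 and 6 and 715 for wild type at day 2. A pseudocount 4 times higher gave 100, 52 and 200 for Eed-null at days 0, 2 and 6, 9, 187 and 83 for Ezh2-null at days 2, 6 and 8, 103 and 43 between the mutants at days 0 and 6, and 196, 743 and 859 for wild type at days 2, 6 and 8. The same setting gave 188 and 279 for the interactions, and 679, 995, 1945 and 2152 for T-GFP, Sox1-GFP, neuronal stem cells and fibroblasts. With the mean of all probe sets the counts were 177 and 92 for Eed-null at days 0 and 2 and 172 and 64 between the mutants at days 0 and 6.

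At 1.5-fold the counts were 44, 73, 1483 and 291 for Ezh2-null at days 0, 2, 6 and 8, 1715, 435 and 1266 for Eed-null at days 0, 2 and 6, and 1666 and 393 between the mutants. They were 1659, 3617 and 3646 for wild type, 1417 and 1789 for the interactions, and 3247, 3736, 5677 and 5638 for the other cell types. With no minimum fold they were 111, 130, 3422 and 340, then 5779, 609 and 2090, then 5524 and 588, then 4713, 7882 and 5852, then 2249 and 2466, and 5521, 6268, 8044 and 7716. The overlap of the mutants' calls was then 61 at day 0 and 1350 at day 6.

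Cell line as a random block (consensus correlation 0.224) gave 4 for Ezh2-null at day 2 and 51 between the mutants at day 6. The replicate block, where the numbers do not pair the arrays (correlations from -0.02 to 0.28 for Ezh2-null at day 0, -0.04 to 0.05 and -0.17 to 0.02 for Eed-null at days 2 and 6 and -0.14 to 0.08 between the mutants at day 6), gave 17, 540, 841 and 885. Where they were read as pairs, it moved no count over 1.5 times. J1 arrays alone as the wild type gave 215 and 39 for Ezh2-null at days 0 and 2, 595 and 555 for Eed-null at days 0 and 2, 822 for wild type at day 2 and 659 and 1039 for the interactions. CJ7 arrays alone gave 16, 116 and 655 for Ezh2-null at days 0, 2 and 6, 1031 for wild type at day 2 and 694 for the Ezh2-null interaction. For Ezh2-null at day 0, E14tg1 alone gave 17, leaving E14tg1 out 46 and wild-type replicates 4 to 7 alone 26. The first array set alone gave 50 for Ezh2-null at day 2 and 272 for its interaction. The second gave 948 for wild type at day 2, 105 and 779 for Ezh2-null at days 2 and 6, 235 between the mutants at day 6 and 831 for the Ezh2-null interaction.

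With 1 array left out the counts ranged from 5 to 17 for Ezh2-null at day 0, 65 to 172 for Eed-null at day 2, 46 to 110 for Ezh2-null at day 8 and 60 to 144 between the mutants at day 6. A lone array left in a group is assumed to vary like the others. Of the 96 list calls 35 held with an estimated correlation, 88 with fry, 90 after quantile normalisation and 88 with the mean of all probe sets. At day 0 in Ezh2-null cells the uncalled difference of Pou5f1 became -0.03 with array weights, 0.00 after quantile normalisation, -0.02 against E14tg1 and -0.02 against wild-type replicates 4 to 7, and that of Sox2 -0.01 against CJ7. Eed in Eed-null cells at day 2 became -0.02 with the mean of all probe sets. The median of p53 targets in Ezh2-null cells at day 2 was 0.00 within the first set. Signal over background limits dim genes, as the change between pseudocounts shows.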

Other observations

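The test on Y-linked genes given above was chosen after the result was seen, and the values here come with no tested explanation. Some single genes of the Polycomb complexes and of DNA methylation differed between ES cells and the 4 differentiated cell types (n = 2, 3, 2 and 2, against 7). Jarid2, a cofactor of PRC2, was lower by the fold minimum or more in T-GFP cells (-1.82 ± 0.19), Sox1-GFP cells (-1.27 ± 0.16), neuronal stem cells (-2.79 ± 0.19) and fibroblasts (-4.05 ± 0.19). Mtf2, another cofactor, was lower as well (-1.57 ± 0.19, -1.20 ± 0.17, -3.10 ± 0.19 and -2.86 ± 0.19). Eed was lower in each (-1.01 ± 0.17, -1.37 ± 0.15, -1.60 ± 0.17 and -2.80 ± 0.17), but with the mean of all probe sets only the call in fibroblasts held (-0.53, -0.68 and -0.85 in the others). In T-GFP cells the call was also lost after quantile normalization (-0.99) and with a pseudocount 4 times higher (-0.95). Ezh2 was called in fibroblasts (-1.37 ± 0.18) and not in neuronal stem cells (-0.40 ± 0.18). Of the 11 PRC2 genes 3, 4, 3 and 5 were lower and none higher. The list passed with the preset correlation (adjusted p = 0.0062, 0.047, 0.028 and 0.0098) and in no cell type with an estimated one (adjusted p = 0.081, 0.27, 0.17 and 0.15). Of the PRC1 genes, Bmi1 was higher (1.24 ± 0.32, 2.75 ± 0.27, 3.68 ± 0.32 and 2.86 ± 0.32; in T-GFP cells 0.88 and not called with a pseudocount 4 times higher) and Phc1 lower (-1.34 ± 0.18, -1.23 ± 0.15, -2.42 ± 0.18 and -3.16 ± 0.18). Dnmt3l (-3.61 ± 0.31, -4.22 ± 0.27, -5.08 ± 0.31 and -4.07 ± 0.31) and the 5-methylcytosine oxidase Tet1 (-2.68 ± 0.31, -2.07 ± 0.26, -2.39 ± 0.31 and -4.61 ± 0.31) were lower in all 4.

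Some genes of the mutants at day 6 lay outside the range between wild-type day 0 and day 6. The Ezh2-null mean on the log2 scale was 9.15 for Zic1, against 5.65 in wild type at day 0 and 5.90 at day 6, and 10.39 for Parm1, against 6.55 and 7.29. Cdkn2a stood at 8.81 against 5.52 and 6.19. Psmb10 lay below both, at 6.76 against 8.39 and 9.75, and in Eed-null cells at 6.56. Esx1 reached 9.71 in Eed-null cells, against 6.31 and 6.35 in wild type. Within wild type at day 6, the second array set exceeded the first by 2.39 for Mixl1 and 1.98 for Fgf8 and lay lower for the globin Hbb-bh1 (-5.30, adjusted p = 1.7e-24).

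The Y-linked gene Eif2s3y was 15 and 9.2 in Ezh2-null replicates 3 and 4 at day 2 and 14.8 and 12.9 in replicates 4 and 5 at day 6. It was 588.9 and 539.6 in Ezh2-null replicates 1 and 2 at day 2. In wild-type cells at day 0 it was 104.8, 79.1 and 60.6 in replicates 1 to 3 and 528 to 578.5 in replicates 4 to 7. Uty followed the same arrays, with 13.6 and 12.8 in Ezh2-null replicates 3 and 4 at day 2 and 27.8 to 57.7 in wild-type replicates 1 to 3 at day 0. Whether these cultures lost the Y chromosome was not tested. Nor was it tested whether the wild-type ones are of another line than their labels give. The labels of the Ezh2-null ones name no line, and whether they differ in line from the other Ezh2-null cultures was not tested either. That doubt bears on the Ezh2-null groups of days 2 and 6 and on wild type at day 0, whose means include these arrays.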
